A study of Toxoplasma gondii with 6 samples.

How the data were processed

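RNA of Toxoplasma gondii oocysts (CZ clone H3), enriched from cat faeces by flotation on sucrose and on a caesium chloride gradient, was enriched for mRNA, made into TruSeq libraries and sequenced on an Illumina HiSeq instrument. The 6 libraries formed 3 groups of 2: unsporulated, sporulating (8 h in 2% sulphuric acid) and sporulated (8 days). The submitters' notes name fastp, Salmon and DESeq2 without versions or order, and the gene identifiers are those of strain ME49 in ToxoDB release 68.

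The authors deposited log2 values, the log2 of the normalized count plus 1, for 8192 genes. After the log was undone, 100% of the values in each library were whole multiples of 1 step per library (tolerance 0.01), which is what a whole read count divided by 1 size factor per library gives. The size factors read from these steps were 0.701, 0.994, 0.764, 0.623, 1.96 and 1.86 in the order unsporulated, sporulating, sporulated. Recovered reads came to 59294254 to 84083923 per library. Salmon's estimated counts can share reads between near-identical genes, so values of gene copies, such as those of ribosomal RNA, are uncertain. Floors for genes without reads cover counting error only, and PCR copies are not independent molecules. The authors also deposited log2 fold changes with p-values and adjusted p-values (the p_value columns of their DESeq2 comparisons) for the 3 pairs of groups. These authors' tables served only as an alternative. Their 3 tables of 1 group against both others were not used, since they combine the same pairs.

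The deposited log2 values were tested as given with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a mean-variance trend, two-sided), with all 6 libraries in 1 model of the 3 groups. Genes with a mean normalized count of at least 10 over the 6 libraries entered, 7813 in all. The p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. There were 35 gene lists, matched by product name or identifier, and 32 of them with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated per list was run beside it, and no list passed it in any comparison (smallest adjusted p 0.518, 0.562 and 0.482). For each list the members that rose or fell are counted over all tested genes and adjusted over the list alone. Some lists share genes, and the ribosomal RNA list holds 1 processing gene by its name.

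Named genes followed a rule. Per comparison they were the 8 rising and 8 falling genes with the largest log2 change past the threshold, with no overlap of libraries between the groups, a mean of at least 50 in the higher group and a known product. To these came up to 4 members with the largest change from each list past the threshold, or the 2 most abundant members where none passed, and the stage markers given by identifier. The lists, the rule, the comparisons and all alternatives other than those named in the closing section were fixed before the data were examined. Folds are 2 to the power of the log2 change, which is the difference between the mean log2 values of the groups with a pseudocount of 1. A fold against a group without reads is given as a bound at a floor of 3 reads per library. Gene positions and lengths came from a RefSeq table of the TGA4 assembly, in which 7757 of the 8192 identifiers were found. These are lengths of genes with introns.

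The alternatives were a pseudocount of 0.5 or 8, no filter or a filter of 100, upper-quartile, median-ratio or total scaling, no variance trend, only the 4 libraries compared, the replicate number as a block, each library left out in turn, voom on the recovered reads, the authors' tables, a fold of at least 2 and unadjusted p-values. With 1 library left in a group, that library is assumed to vary like the others. The whole procedure was tested on simulated data with 50 genes planted at each of 4 sizes. At a log2 change of 1, between 2% and 4% of planted genes were called, and at 2 between 42% and 56%. At 3 it was between 80% and 88% and at 5 between 90% and 94%, with 5 to 8 false calls per comparison. Few simulated genes changed, and they varied independently of each other. The rates therefore need not hold where most genes changed or where genes vary together. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.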

Results

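Messenger RNA was sequenced from oocysts of Toxoplasma gondii (CZ clone H3), the walled stage that cats shed and that becomes infectious by sporulation, the formation of sporozoites inside the wall. There were 3 groups of 2 libraries each. Unsporulated oocysts were preserved in lysis reagent after purification from faeces. Sporulating oocysts were collected 8 h after transfer to 2% sulphuric acid, and sporulated oocysts after 8 days. The table held 8192 genes, of which 7974 were protein-coding. Whole reads recovered from the values came to 59294254 and 84083923 in the unsporulated libraries, 82646013 and 78347152 in the sporulating libraries, and 76673634 and 80320300 in the sporulated libraries. Up to 510 genes had no read in a given library, and counting error alone allows up to 3 reads for such a gene. Group values below are normalized read counts given as mean ± SD (n = 2 libraries per group), and log2 changes carry their SE. Apart from bounds against a group without reads, a fold is 2 to the power of the log2 change, the difference between the mean log2 values of the groups, so it can differ from the ratio of the means shown. Nothing in the labels says whether the 2 libraries of a group came from separate cats or cultures, so the p-values measure only the spread between these samples, which may be technical in part.

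The most abundant transcript of unsporulated and of sporulating oocysts was the same hypothetical protein, TGME49_202110, with 4.05 ± 0.541% and 3.74 ± 0.349% of the reads. In sporulated oocysts it was another hypothetical protein, TGME49_210682, with 6.28 ± 0.439%. OWP2, an oocyst wall protein, took 1.08 ± 0.272% of the reads in sporulating oocysts. In sporulated oocysts the surface antigens SRS25 and SAG3 took 2.25 ± 0.00359% and 2.08 ± 0.0848%, and the dense granule proteins GRA1 and GRA7 took 2.09 ± 0.000719% and 1.64 ± 0.118%. The first principal component of the 7813 tested genes held 86.7% of the variance and set both sporulated libraries apart from the other 4. Across genes, which are not independent replicates, the log2 values of sporulated and unsporulated libraries had Pearson correlations of 0.391 to 0.434. Unsporulated library 1 correlated with sporulating library 1 (0.965) as closely as with unsporulated library 2 (0.964). The median absolute log2 difference between the 2 libraries of a group was 0.51 for sporulating oocysts, against 0.32 for unsporulated and 0.28 for sporulated oocysts.

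**Figure D1:**
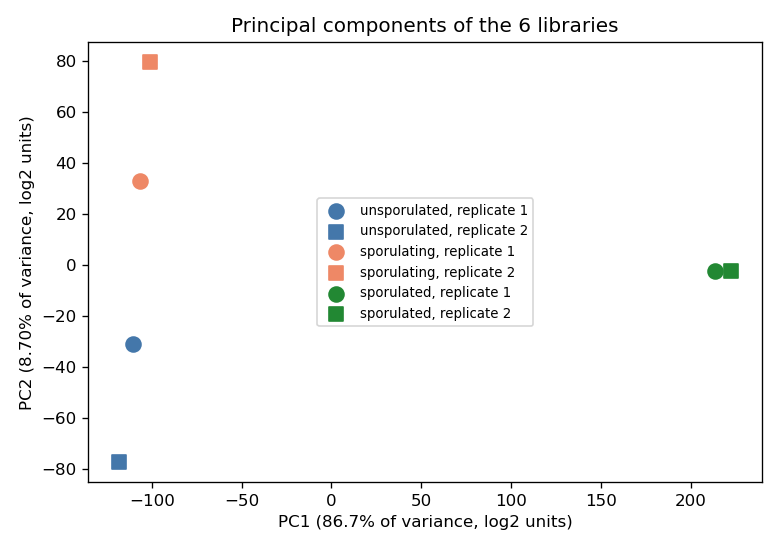
Each point is 1 of the 6 libraries, placed by its first (horizontal, 86.7% of the variance) and second (vertical, 8.70%) principal component of the log2 values of 7813 genes. Both sporulated libraries lie at 213 and 223 on the first component, and the 4 others lie between -118 and -101.

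The comparison of sporulating with unsporulated oocysts asked which transcripts had changed 8 h after sporulation was started. Several transcripts of the oocyst wall, 2 of late embryogenesis abundant (LEA) proteins, which protect cells during drying, and that of the sporozoite surface antigen SporoSAG were higher at 8 h. OWP2 (TGME49_209610, chromosome Ib, 1359383 to 1361739 in the TGA4 assembly) rose 2.52-fold, from 489195 ± 35583 to 1274036 ± 450589 (log2 change 1.34, SE 0.27, limma adjusted p = 0.044). OWP1 (TGME49_204420) rose from 3221 ± 3562 to 51635 ± 29717, a log2 change of 4.55 (SE 0.90). OWP3 (TGME49_268310) rose by 2.25 (SE 0.41), and a further wall protein, TGME49_210950, by 4.28 (SE 0.92). Of the 7 oocyst wall proteins 4 rose and 3 did not pass, with 5 rising when adjusted over the list alone. As a list they were not called (median log2 change 2.25, camera adjusted p = 0.0591). Of 4 LEA proteins 2 rose, and 3 rose when adjusted over the list alone. LEA850 (TGME49_276850) rose from 1206 ± 1221 to 17778 ± 14526, and LEA880 (TGME49_276880) rose by 4.12 on the log2 scale (SE 0.89). SporoSAG (TGME49_258550) rose 12.1-fold, from 2303 ± 1740 to 28072 ± 21656. AMA3, the other sporozoite marker among the deposited genes, was at 33435 ± 2108 against 24441 ± 2541 (log2 change 0.45, limma adjusted p = 0.177). Sporulating library 2 lay above library 1 by a median of 1.22 on the log2 scale over the wall proteins and 1.27 over the LEA proteins, and unsporulated library 2 lay below library 1 by 0.20 and 1.44.

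Several lists of genes of the organelles that sporozoites use to move and to enter host cells were higher at 8 h. Rhoptry bulb proteins, which are injected into the host cell, rose in 19 of 57 cases, and none fell. Adjusted over the list alone, 31 rose and 1 fell. Their median log2 change was 2.02, or 1.98 with members without reads in a group at their bound (camera adjusted p = 1.26e-07, adjusted p = 0.518 with an estimated correlation). ROP5 (TGME49_308090), a pseudokinase and virulence factor, rose 20.2-fold, from 1216 ± 1365 to 17041 ± 11566. ROP2A rose from 6.88 ± 1.65 to 129 ± 64.4, and ROP14 from 36.8 ± 44.9 to 458 ± 181. Of 19 apical membrane antigens and rhoptry neck proteins, which form the moving junction at invasion, 8 rose and none fell, with 11 rising when adjusted over the list alone. Their median change was 1.46 (camera adjusted p = 9.13e-05, adjusted p = 0.518 with an estimated correlation). The sporozoite form of RON2 (TGME49_500398) rose 14.3-fold, from 744 ± 745 to 7934 ± 3588, and RON2L1 rose by 4.48 on the log2 scale (SE 0.90). Inner membrane complex proteins, which build the pellicle of the zoite, rose in 12 of 46 cases and fell in 1, or 27 and 1 adjusted over the list alone. Their median change was 1.16 (camera adjusted p = 5.95e-05, adjusted p = 0.518 with an estimated correlation). IMC24 rose from 199 ± 157 to 2564 ± 2110, and IMC16 rose by 3.25 (SE 0.57). Sporulating library 2 lay above library 1 in 43 of the 57 rhoptry bulb genes (median 0.83), in 17 of the 19 neck and antigen genes (median 0.92) and in 36 of the 46 pellicle genes (median 0.57). Without sporulating replicate 2 the median of the neck and antigen list was 0.89 (adjusted p = 0.00117). With every library scaled to the same total, all log2 changes at 8 h shifted by -0.46, and the medians of the 3 lists became 1.56, 1.0 and 0.71.

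Some proteases and motility genes were higher too, and as in the lists above most members did not pass. Of 34 proteases of secretory organelles 9 rose and none fell, or 17 and 1 adjusted over the list alone. Their median change was 0.72, or 0.27 under total scaling (camera adjusted p = 9.13e-05, adjusted p = 0.518 with an estimated correlation). ASP3, which matures rhoptry and microneme proteins, rose 3.30-fold, from 113 ± 22.6 to 373 ± 62.6. The cathepsin CPC3 rose from 70597 ± 2617 to 187090 ± 70625, and the subtilisin SUB8 rose by 2.10 (SE 0.42). In the gliding motor list 8 of 39 members rose and none fell, or 13 and 2 adjusted over the list alone. The median was 0.65, 0.52 with members without reads at their bound and 0.19 under total scaling (camera adjusted p = 0.0345, adjusted p = 0.518 with an estimated correlation). Without sporulating replicate 2 it was 0.34, with an adjusted p of 0.120. GAPM1A rose by 4.66 (SE 1.10), and GAC, which links adhesins to actin, rose 6.10-fold, from 49.7 ± 34.7 to 292 ± 159. Microneme proteins were not called as a list: 3 of 30 rose, none fell, and 5 rose adjusted over the list alone, with a median of 0.38 that became -0.02 under total scaling (camera adjusted p = 0.0579). MIC1, an adhesin, was among the 3 and rose from 166 ± 124 to 2158 ± 1709. Of 78 dense granule proteins 5 rose and none fell, none of either when adjusted over the list alone, with a median of 0.25 that became -0.21 under total scaling (camera adjusted p = 0.146). GRA33 (TGME49_247440) rose 29.8-fold, from 289 ± 330 to 5905 ± 4166. Among other genes with a known product, the kinase-like protein TGME49_321710 rose by 5.04 (SE 0.59), from 8.22 ± 4.52 to 309 ± 172. The MtN3-type transporter TGME49_300250 had no read in either unsporulated library, and 29 and 165 reads in the sporulating libraries. Redox enzymes rose in 6 of 46 cases and fell in 1, the same counts adjusted over the list alone, with a median of 0.03 that became -0.43 under total scaling (camera adjusted p = 0.681). They included the superoxide dismutase SOD3, from 3037 ± 3154 to 41083 ± 24420, and the peroxiredoxin PRX2, from 199.9 ± 192 to 2078 ± 887.

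The list of DNA replication genes was lower at 8 h. Of 34 members 5 fell and none rose, the same counts adjusted over the list alone. The median was -0.25, -0.18 with the member without reads at its bound and -0.63 under total scaling (camera adjusted p = 0.0382, adjusted p = 0.544 with an estimated correlation). Subunits of the origin recognition complex, which marks replication origins, were among them. ORC1 fell 2.72-fold, from 1024 ± 10.7 to 388 ± 133, and ORC3 fell by 1.73 on the log2 scale (SE 0.40). Cytosolic ribosomal protein genes had a median of -0.24 over 88 members, or -0.70 under total scaling (camera adjusted p = 0.0382, adjusted p = 0.778 with an estimated correlation). Even so, 2 single members rose and none fell, and 1 rose adjusted over the list alone. Those 2 were RPS20, from 3.15 ± 1.61 to 33.3 ± 8.49, and RPS15A, from 5.87 ± 0.230 to 32.5 ± 10.8. Of 67 AP2 factors, DNA-binding regulators of parasite stages, 3 rose and 1 fell, or 8 and 3 adjusted over the list alone, with a median of 0.16 that became -0.29 under total scaling (camera adjusted p = 0.592). AP2VIII-7 (TGME49_269010) rose by 3.27 (SE 0.75) and AP2VIII-2 (TGME49_233120) fell 4.19-fold, from 1076 ± 196 to 254 ± 1.70. At the deposited scaling the changes of the DNA replication and ribosomal lists were no larger than differences within a group. Sporulating library 2 lay below library 1 by a median of 0.37 over the DNA replication genes (10 of 34 higher) and 0.28 over the ribosomal genes (24 of 88 higher). Unsporulated library 2 lay above library 1 by 0.20 over the latter. The DNA replication median was -0.22 without unsporulated replicate 1 (adjusted p = 0.0678), -0.08 without sporulating replicate 2 (0.168) and -0.49 without sporulating replicate 1 (0.016). The ribosomal median was -0.07 without unsporulated replicate 2 (0.174), -0.17 without sporulating replicate 2 (0.191) and -0.36 without unsporulated replicate 1 (0.00625), and its adjusted p was 0.0613 when no variance trend was fitted.

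By limma 794 of 7813 tested genes (10.2%) changed at 8 h, 644 of them up and 150 down, and 751 of them changed at least 2-fold. The adjusted p of these genes lay between 0.044 and 0.0499, close under the threshold of 0.05. The authors' DESeq2 table had 1670 genes past the same threshold, which held all 794 in the same direction. No gene passed without sporulating replicate 2 (1661 genes at an unadjusted p under 0.05), without sporulated replicate 1 (2020) or replicate 2 (2012), or with libraries scaled to the same total (3064). The count was 174 without unsporulated replicate 2 and 1632 without sporulating replicate 1.

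**Figure D2:**
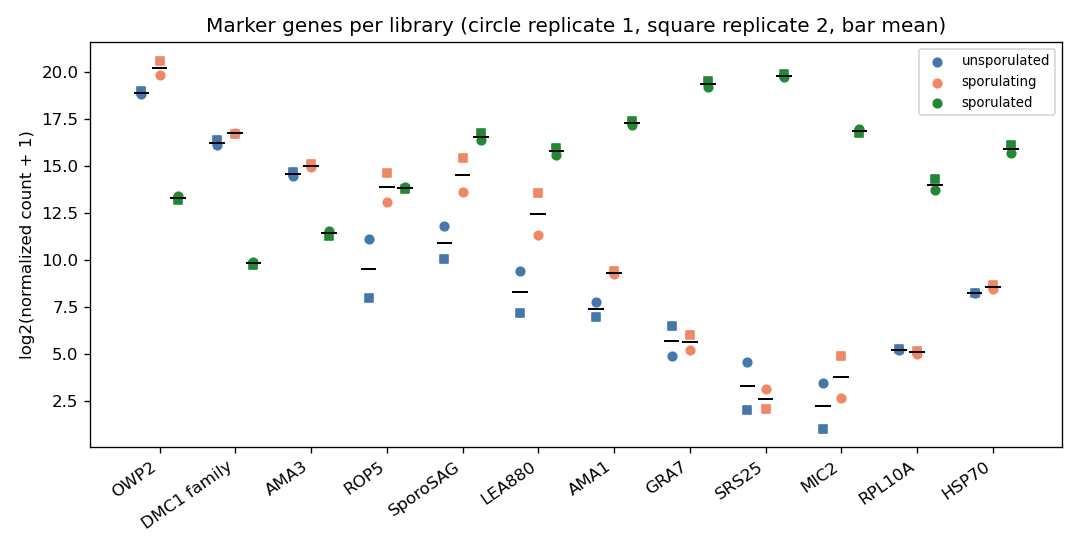
Log2 of the normalized count plus 1 (vertical) of single genes (horizontal) in the unsporulated, sporulating and sporulated groups, with 1 point per library and a bar at the mean of the 2 log2 values. OWP2 was highest in the sporulating libraries, and SRS25 went from a normalized count of 5.53 ± 3.29 in sporulating to 926748 ± 64906 in sporulated oocysts.

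The comparison of sporulated with sporulating oocysts asked what had changed between 8 h and 8 days, when sporulation was complete. Microneme and dense granule transcripts, which the sporozoite needs to invade and to remodel its host cell, were higher as lists. Surface antigens of the SRS family went both ways, with 31 of 96 up and 36 down, or 31 and 35 adjusted over the list alone (median log2 change -0.73, or 1.10 under total scaling, camera adjusted p = 0.658). SRS25 (TGME49_213280, chromosome V, 892962 to 895548 in the TGA4 assembly), of that family, had the largest rise under the naming rule, with a log2 change of 17.21 (SE 0.81, limma adjusted p = 2.9e-06). SAG3, a surface antigen that binds host glycans, rose from 235 ± 86.7 to 857816 ± 96206. Of 30 microneme proteins 22 rose and 3 fell, the same counts adjusted over the list alone, with a median log2 change of 5.41 (camera adjusted p = 0.00182, adjusted p = 0.562 with an estimated correlation). The adhesin MIC2 rose from 17.1 ± 16.7 to 118399 ± 11512, its partner M2AP from 26.4 ± 5.82 to 152764 ± 13215, and MIC10 from 386 ± 135 to 560731 ± 92787. Of 78 dense granule proteins, which are secreted into the vacuole, 58 rose and 9 fell, the same counts adjusted over the list alone. Their median was 4.99, or 4.80 with members without reads at their bound (camera adjusted p = 4.93e-06, adjusted p = 0.562 with an estimated correlation). GRA7 rose by 13.74 (SE 0.54) and GRA25 from 3.93 ± 5.55 to 71192 ± 5987. Rhoptry bulb proteins rose in 29 of 57 cases and fell in 3, the same counts adjusted over the list alone, with a median of 2.16 (camera adjusted p = 0.00917, adjusted p = 0.571 with an estimated correlation). ROP34 rose from 8.81 ± 7.91 to 33977 ± 666. The camera adjusted p of the rhoptry list was 0.059 without sporulating replicate 1.

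Most ribosome genes rose as well. Of 88 cytosolic ribosomal proteins 60 rose and 11 fell, the same counts adjusted over the list alone, with a median log2 change of 2.51 (camera adjusted p = 8.21e-05, adjusted p = 0.605 with an estimated correlation). RPL10A rose 483-fold, from 33.4 ± 2.74 to 16936 ± 5058, RPL31 from 11.2 ± 4.51 to 7562 ± 2277, and RPL35A by 9.98 (SE 0.69). The ribosomal genes were higher in sporulated library 2 than in library 1 in 79 of 88 cases (median 0.51), and lay above the sporulating mean by medians of 2.34 in library 1 and 2.65 in library 2. Of 36 ribosome biogenesis genes 24 rose and 6 fell, the same counts adjusted over the list alone, with a median of 2.68 (camera adjusted p = 0.00917, adjusted p = 0.562 with an estimated correlation). The nucleolar protein TGME49_205510 rose from 24.7 ± 7.68 to 3834 ± 505. All 4 LEA proteins rose, also adjusted over the list alone, with a median of 3.24. LEA860 (TGME49_276860) rose 48.8-fold, from 1409 ± 433 to 67625 ± 10805. The calls of LEA850 and LEA880 were lost without sporulating replicate 1 (adjusted p = 0.248 and 0.0753), without sporulated replicate 1 (0.179 and 0.0783) and without sporulated replicate 2 (0.194 and 0.105), and that of LEA850 also without a variance trend (0.0746). Heat shock proteins and chaperones were not called as a list (36 of 64 rose and 15 fell, the same counts adjusted over the list alone, median 1.30, camera adjusted p = 0.0571). HSP70 rose by 7.32 (SE 0.25) and the small heat shock protein HSP29 by 8.40 (SE 0.50).

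Meiosis genes fell together. All 5 tested members of the meiosis and recombination list fell, also adjusted over the list alone, with a median log2 change of -6.91 (camera adjusted p = 0.00917, adjusted p = 0.562 with an estimated correlation). The gene of the DMC1 family, the recombinase of meiotic crossing over (TGME49_216400, chromosome XI, 6170141 to 6172278 in the TGA4 assembly), fell 121-fold, from 109027 ± 462 to 904 ± 56.6. A Mnd1 family gene, whose product assists DMC1, fell by 7.21 on the log2 scale (SE 0.30). Wall transcripts fell too, 5 of 7 with 1 rise, the same counts adjusted over the list alone (median -3.79, camera adjusted p = 0.234 for the list). OWP2 fell 122-fold to 10166 ± 994, and OWP3 fell 19.2-fold, from 15834 ± 8967 to 758 ± 97.8. Secretory proteases went both ways, with 11 of 34 up and 20 down, the same counts adjusted over the list alone (median -2.03, or -0.53 under total scaling, camera adjusted p = 0.0805). CPC3 fell by 7.40 (SE 0.28) to 1067 ± 57.3, the rhomboid protease ROM3 fell 197-fold, from 84698 ± 23547 to 419.6 ± 5.93, and the cathepsin CPC1 rose 209-fold, from 73.8 ± 36.3 to 14663 ± 343. Of the flagellum and microgamete list 18 of 33 members fell and 5 rose, the same counts adjusted over the list alone (median -1.56, or -0.06 under total scaling, camera adjusted p = 0.0822). They included IFT81, of flagellar transport, which fell from 1831 ± 58.3 to 56.0 ± 18.1. Among apical antigens and rhoptry neck proteins 5 of 19 rose and 2 fell, the same counts adjusted over the list alone (median 0.82, camera adjusted p = 0.584). AMA1 rose 253-fold to 161924 ± 18051, and AMA3 fell 12.2-fold to 2742 ± 394. Inner membrane complex proteins rose in 24 of 46 cases and fell in 7, the same counts adjusted over the list alone (median 1.30, camera adjusted p = 0.0571). The gliding motor list had 23 of 39 up and 7 down, the same counts adjusted over the list alone (median 2.21, camera adjusted p = 0.0658). IMC18 rose from 51.2 ± 20.6 to 39984 ± 6947, and GAP80 from 87.0 ± 6.34 to 52288 ± 7099.

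By limma 5993 of 7813 genes (76.7%) changed in this comparison, with 3141 up and 2852 down. The authors' DESeq2 table had 6089, and 5937 were called in both in the same direction. The direction of many smaller changes depends on the scaling: sporulated libraries needed size factors of 1.96 and 1.86, against 0.623 to 0.994 for the other 4. With every library scaled to the same total, all log2 changes shifted by 1.50 and the split became 4480 up and 1752 down.

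**Figure D3:**
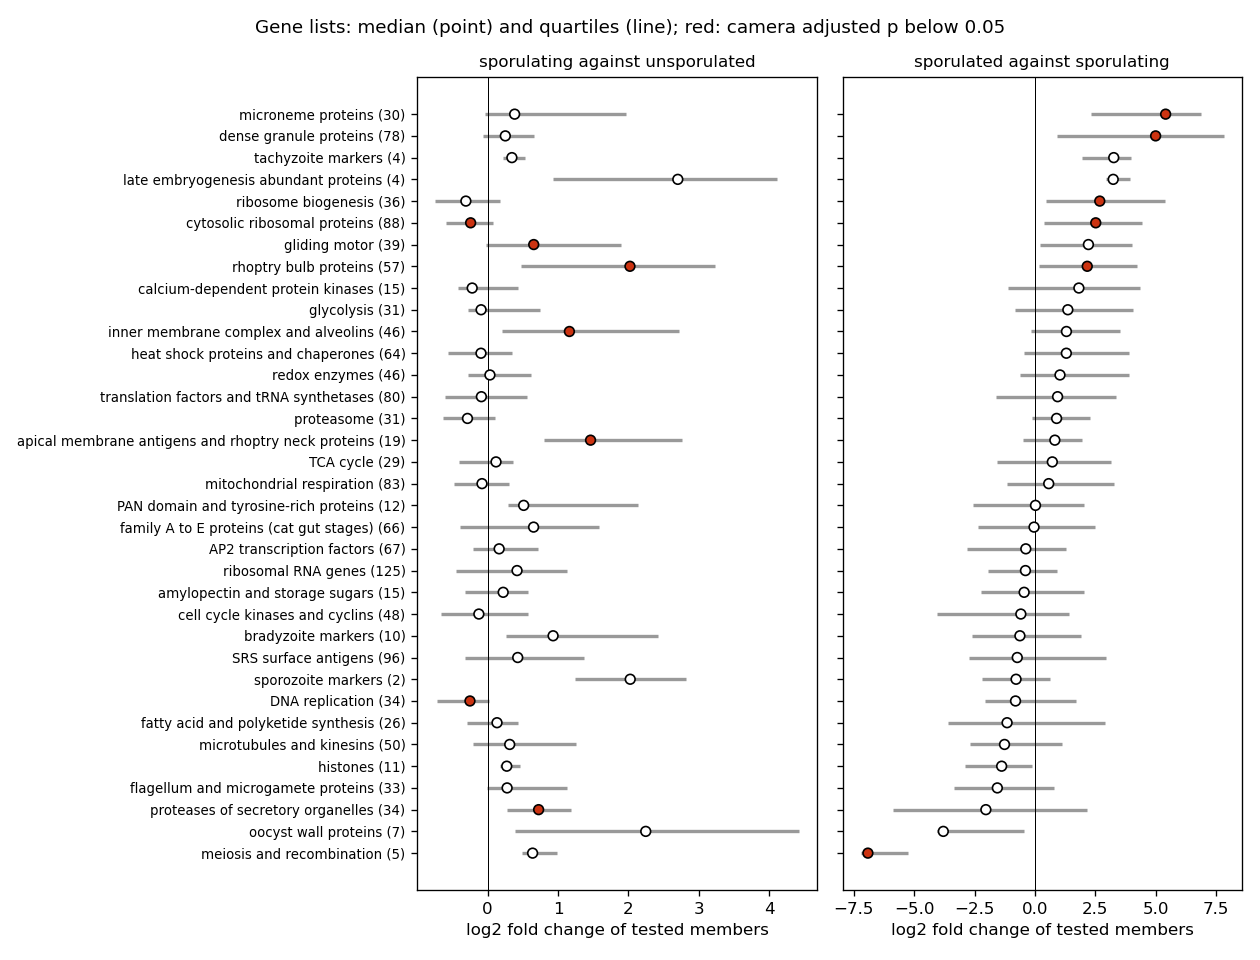
Median log2 change (points, horizontal) of the 35 gene lists (vertical, tested members in brackets) for sporulating against unsporulated and sporulated against sporulating oocysts, with lines from the lower to the upper quartile and red points for a camera adjusted p below 0.05 at the preset correlation. With an estimated correlation no list passed in these comparisons (smallest adjusted p 0.518 and 0.562). Rhoptry bulb proteins had medians of 2.02 and 2.16, microneme proteins 0.38 (-0.02 under total scaling) and 5.41, and meiosis genes 0.64 (0.18 under total scaling) and -6.91. Several lists with small medians, such as SRS antigens, histones and AP2 factors, change direction under total scaling.

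The comparison of sporulated with unsporulated oocysts spanned the whole process. Lists of rhoptry, microneme, dense granule and pellicle genes were higher after 8 days. Of 57 rhoptry bulb proteins 47 rose and 1 fell, the same counts adjusted over the list alone, with a median log2 change of 4.61 (camera adjusted p = 3.7e-06, adjusted p = 0.482 with an estimated correlation). ROP35, a kinase, rose from 13.3 ± 16.8 to 13760 ± 1424. Of 30 microneme proteins 23 rose and 2 fell, the same counts adjusted over the list alone, with a median of 6.48 (camera adjusted p = 0.0003, adjusted p = 0.482 with an estimated correlation). M2AP had a log2 change of 15.40 (SE 1.04). Of 78 dense granule proteins 58 rose and 9 fell, or 59 and 9 adjusted over the list alone, with a median of 5.76 (camera adjusted p = 8.34e-07, adjusted p = 0.482 with an estimated correlation). Inner membrane complex proteins rose in 32 of 46 cases and fell in 5, the same counts adjusted over the list alone, with a median of 3.53 (camera adjusted p = 0.00135, adjusted p = 0.482 with an estimated correlation). IMC24 rose from 199 ± 157 to 344680 ± 40901. Gliding motor genes rose in 24 of 39 cases and fell in 7, the same counts adjusted over the list alone. Their median was 3.57, or 3.38 with members without reads at their bound (camera adjusted p = 0.024, adjusted p = 0.50 with an estimated correlation). GAC rose 303-fold, from 49.7 ± 34.7 to 13662 ± 3446. Apical antigens and rhoptry neck proteins rose in 16 of 19 cases and fell in 2, the same counts adjusted over the list alone, with a median of 3.04 (camera adjusted p = 0.0468, adjusted p = 0.681 with an estimated correlation). AMA1 rose 979-fold, from 170.3 ± 65.9 to 161924 ± 18051.

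LEA proteins and most ribosome genes also rose over the whole process, and meiosis genes fell. All 4 LEA proteins rose, also adjusted over the list alone, with a median log2 change of 6.71, and LEA880 rose 177-fold, from 418 ± 388 to 56628 ± 10679. SporoSAG rose by 5.64 on the log2 scale (SE 0.70), to 98249 ± 18700. Of 88 ribosomal proteins 55 rose and 12 fell, the same counts adjusted over the list alone, with a median of 2.16 (camera adjusted p = 0.000347, adjusted p = 0.681 with an estimated correlation). RPS20 rose from 3.15 ± 1.61 to 4658 ± 823. Of 36 ribosome biogenesis genes 23 rose and 8 fell, the same counts adjusted over the list alone, with a median of 2.27 (camera adjusted p = 0.024, adjusted p = 0.482 with an estimated correlation). All 5 meiosis genes fell, also adjusted over the list alone, with a median of -5.92 (camera adjusted p = 0.0112, adjusted p = 0.482 with an estimated correlation). Oocyst wall proteins had 1 rise and 3 falls among 7, the same counts adjusted over the list alone, with a median of 0.46 although camera's direction was down (adjusted p = 0.595). The rise was TROWP (TGME49_319890), a tyrosine-rich wall protein, from 46.4 ± 65.6 to 19164 ± 1857, and OWP2 fell 48.2-fold. MAF1a, of a family of proteins in the vacuole membrane, had no read in either unsporulated library and was at least 10694-fold higher in sporulated oocysts, at a floor of 3 reads per library.

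By limma 5981 of 7813 genes (76.6%) changed between unsporulated and sporulated oocysts, with 3161 up and 2820 down. The authors' DESeq2 table had 6066, and 5936 were called in both in the same direction. Total scaling shifted all log2 changes by 1.04, gave a split of 4178 up and 2021 down, and ended the list calls of the neck and antigen genes (adjusted p = 0.0798), ribosome biogenesis (0.0608) and the gliding motor (0.0608). Without sporulated replicate 1 the adjusted p was 0.091 for the neck and antigen list and 0.056 for the gliding motor, and without sporulating replicate 2 it was 0.0502 for the former. The neck and antigen list also missed the threshold with a pseudocount of 8 (0.0531), upper-quartile scaling (0.0559), no variance trend (0.0574) and only the 4 libraries compared (0.0549).

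The last question was which genes had risen at 8 h and fallen again by 8 days. There were 310 such genes, 48.1% of the 644 that rose at 8 h. OWP2, OWP3, CPC3, IFT81 and the Mnd1 family gene were among them, as was the putative alpha-amylase AMY3 (TGME49_283490), of a class of enzymes that cut starch. AMY3 rose 2.62-fold, from 11171 ± 1780 to 29172 ± 2729, and then fell 209-fold to 139 ± 15.0. OWP1 and TGME49_210950 were also called in both steps, with falls of 3.79 and 3.82 whose adjusted p rose to 0.0614 and 0.0629 without sporulating replicate 2. For OWP1 it rose to 0.0677 without sporulated replicate 1 and 0.0747 without replicate 2, and for TGME49_210950 to 0.056 and 0.0865. A further 177 genes rose in both steps, among them BFD1, a regulator of the cyst stage, from 435 ± 64.9 to 1330 ± 569.7 and then to 4874 ± 59.7. There were 97 genes that fell at 8 h and rose by 8 days, and 27 that fell in both steps. With independent steps 235 transient rises and 60.3 transient falls would be expected. Both steps share the sporulating libraries, which tie them together: in 50 simulations of unchanged groups no gene was called in both, but the top genes in the same numbers overlapped by 478 (455 to 500) for rises and 127 (114 to 137) for falls. The simulated groups did not change, whereas 5993 of 7813 genes changed in the second step, so 478 and 127 are not the overlaps to be expected here. With shared libraries the independent number is no fair reference either. An overlap above it therefore gives no separate evidence of transient genes. Without unsporulated replicate 1 there were 157 transient rises and 18 falls, and without unsporulated replicate 2 there were 75 and 3. Without sporulating replicate 1 the counts were 409 and 516, and none of either remained without sporulating replicate 2 or without either sporulated library.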

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

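Total scaling, voom on the recovered reads and the count at an unadjusted p were chosen after the data had been seen. The limma counts at 8 h depend on the processing: the 794 changed genes became 0 with no filter, with only the 4 libraries compared and with total scaling, 10 without the variance trend, 1670 in the authors' DESeq2 tables and 2563 at an unadjusted p. They ranged from 0 to 1632 over leave-one-out fits. The smallest adjusted p was 0.0508 without the filter, 0.0505 with total scaling and 0.0845 with 4 libraries, so calls near the threshold were lost together, with 2586, 3064 and 2086 genes at an unadjusted p under 0.05. No setting turned the sign of any of the 794. Transient rises (310) became 0 with no filter, 4 libraries or total scaling, 1 without the trend, 473 with voom and 540 in the authors' tables, and 0 to 409 over leave-one-out fits. Transient falls (97) became 0 in those same 3 settings, 3 without the trend, 153 with a pseudocount of 8, 352 in the authors' tables and 0 to 516 over leave-one-out fits. The 7 lists called at 8 h became 12 with upper-quartile scaling and 14 with total scaling, and 7 to 11 over leave-one-out fits, with 11 without unsporulated replicate 1. With an estimated correlation 0 lists were called in each comparison, against 7, 6 and 9. Gene counts in the other 2 comparisons, and their list counts apart from the estimated correlation, stayed within 1.5 times of the reported ones in every setting. Of the named genes, 941 of 2145 alternative results at 8 h were no longer called, 35 of 2692 for sporulated against sporulating and 14 of 2673 for sporulated against unsporulated. One result of a named gene reversed, LDH1 in sporulated against sporulating oocysts, from -0.95 to 0.56 (adjusted p = 0.0223) with total scaling. Over all genes, total scaling turned the sign of 475 of the 5993 calls in that comparison, and 93 were called in the opposite direction. For sporulated against unsporulated oocysts it turned 176 of 5981, with 1 called in the opposite direction. The cause of these changes was not tested, apart from the threshold effect above. Depth limits genes without reads, to which 3 reads per library are allowed.

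With the replicate number as a block, 0 genes changed at 8 h (2583 at an unadjusted p under 0.05, smallest adjusted p 0.0607), with 0 transient rises and 0 transient falls. The calls of LEA850 (adjusted p = 0.0657) and SporoSAG (0.0513) in sporulated against sporulating oocysts, and of the neck and antigen list in sporulated against unsporulated oocysts (0.0517), were lost. Little expression difference was shared by replicate number: across genes, the differences between replicates of 2 groups had correlations of -0.03, 0.10 and -0.004. Whether libraries of the same number share an origin stays unknown.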

Other observations

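The tests of sporulated RNA mixed into the sporulating libraries, of scaling and of progress along the change at 8 h, and the values of the ribosomal list in each sporulated library, were chosen after the result was seen. Stage markers other than those of sporozoites went separate ways. SAG2A, of the tachyzoite list, rose from 290.4 ± 149.7 to 10172 ± 1461 between 8 h and 8 days (limma log2 change 5.22, SE 0.63), and 3 of the 4 tachyzoite markers rose and 1 fell there (adjusted over the list alone as well, median 3.26). At 8 h none of the 4 was called, with 1 rising adjusted over the list alone and a median of 0.34 that became -0.12 under total scaling, and over the whole process 3 rose and none fell (median 3.47). Of 10 bradyzoite markers 3 rose at 8 h, 4 adjusted over the list alone, with a median of 0.93 (camera adjusted p = 0.0579). Between 8 h and 8 days 4 rose and 3 fell, with a median of -0.62 that became 0.86 under total scaling (camera adjusted p = 0.864), and over the whole process 5 rose and 3 fell (median 1.0, camera adjusted p = 0.718). Between 8 h and 8 days the calls of SAG1 (adjusted p = 0.0883) and BRP1 (0.125) were lost without sporulating replicate 1, and that of SRS35A (0.0518) without sporulating replicate 2. Without sporulated replicate 1 the calls of SAG1 (0.105), MAG1 (0.0627), SRS35A (0.0588), LDH2 (0.0577) and BRP1 (0.0919) were lost, and without sporulated replicate 2 those of SAG1 (0.0904), SRS44 (0.0545), SRS35A (0.0726) and BRP1 (0.153). Over the whole process the calls of SAG1, SRS44, LDH2 and the enolase ENO1 were lost without sporulated replicate 2, with adjusted p = 0.0768, 0.0521, 0.0767 and 0.0987, and without sporulated replicate 1 SAG1 (0.0883) and LDH2 (0.112) were lost. LDH2 was also lost there without unsporulated replicate 2 (0.0603) and under total scaling (0.0666), as was SRS44 between 8 h and 8 days under total scaling (0.0735). SRS9 fell 9.21-fold between 8 h and 8 days, from 1244 ± 49.1 to 134 ± 7.06, and BFD1 rose 3.84-fold. BAG1, a small heat shock protein of cysts, had 4.68 ± 1.30 in sporulated against 29.7 ± 32.8 in sporulating oocysts and was not called (adjusted p = 0.145). Of 3 sporozoite markers fixed by identifier only 2, SporoSAG and AMA3, were among the deposited genes. Their medians were 2.02 at 8 h, -0.78 in the second step (0.72 under total scaling) and 1.24 over the whole process. The rise of SporoSAG in the second step (2.05, SE 0.70) was not called without the variance trend (adjusted p = 0.0597), without sporulated replicate 1 (0.126) or 2 (0.188), or without sporulating replicate 1, where it was 1.17 (0.190).

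In sporulated against sporulating oocysts, single genes of metabolism and of the nucleus moved both ways, and camera called none of the lists that follow. Family A to E proteins had 22 up and 22 down of 66 (22 and 21 adjusted over the list alone, median -0.04, or 1.51 under total scaling, camera adjusted p = 0.972). PAN domain and tyrosine-rich proteins had 3 up and 5 down of 12 (median 0.02, adjusted p = 0.640). AP2 factors had 18 up and 27 down of 67 (median -0.38, or 1.12 under total scaling, adjusted p = 0.334), with AP2X-4 up from 31.5 ± 12.8 to 4513 ± 274 and AP2IX-5 down 69.5-fold. Of 11 histones 2 rose and 7 fell (median -1.38, or 0.13 under total scaling, adjusted p = 0.163). The variant H2Bv (TGME49_209910) fell from 280289 ± 10824 to 22261 ± 1525. DNA replication had 13 up and 17 down of 34 (median -0.80, or 0.70 under total scaling, adjusted p = 0.640). Cell cycle kinases and cyclins had 14 up and 23 down of 48 (median -0.58, or 0.91 under total scaling, adjusted p = 0.163), with CYC1 down 176-fold. Microtubules and kinesins had 10 up and 25 down of 50 (median -1.26, or 0.26 under total scaling, adjusted p = 0.0805), with EB1, a plus-end binding protein, down 55.2-fold. Fatty acid and polyketide synthesis had 10 up and 14 down of 26 (median -1.15, or 0.35 under total scaling, adjusted p = 0.237). Amylopectin and storage sugars had 5 up and 7 down of 15 (median -0.45, or 1.06 under total scaling, adjusted p = 0.601). Glycolysis had 19 up and 8 down of 31 (median 1.36, adjusted p = 0.163), with the phosphoglycerate kinase PGKI up 231-fold. The TCA cycle had 14 up and 10 down of 29 (median 0.72, adjusted p = 0.601), with the succinate dehydrogenase subunit SDHB up 62.2-fold and a citrate synthase, TGME49_263130, down 39.5-fold. Mitochondrial respiration had 40 up and 28 down of 83 (41 and 28 over the list alone, median 0.57, adjusted p = 0.315). Redox enzymes had 26 up and 11 down of 46 (median 1.04, adjusted p = 0.163). Translation factors and tRNA synthetases had 39 up and 28 down of 80 (40 and 28 over the list alone, median 0.94, adjusted p = 0.348), and the proteasome 18 up and 7 down of 31 (median 0.90, adjusted p = 0.187). Calcium-dependent protein kinases had 9 up and 5 down of 15 (median 1.82, adjusted p = 0.345), with CDPK2A up 104-fold. Ribosomal RNA genes had 19 up and 25 down of 125 (19 and 21 over the list alone, median -0.39, or 1.23 under total scaling, adjusted p = 0.601), which near-identical copies make uncertain. The mean change had the opposite sign to the median for SRS antigens (0.33), family A to E proteins (0.49), DNA replication (0.04), bradyzoite markers (0.09) and PAN domain and tyrosine-rich proteins (-0.07, with camera's direction down). Where no other count is given, the counts adjusted over the list alone were the same.

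Genes of the rhoptry bulb list were higher in sporulating than in unsporulated oocysts. The values argue against RNA of sporulated oocysts mixed into the sporulating libraries. The 20 most abundant sporulated genes gave a median apparent share of 0.181% (range -10.5 to 8.33%). At that median the list's 57 members would have a median log2 change of 0.0492, or 0.26 at its upper 95% bootstrap bound. The observed median was 2.02 (1.12 to 2.84). At the highest single share 1.38 would be reached, inside that interval. Negative shares cannot come from mixing, so the genes' own changes at 8 h enter the shares. A share that high would also bring in SRS25, MIC2 and M2AP, whose counts at 8 h were very low, as given above. Scaling moves all genes alike, so it cannot give the 1.96 by which the list's median exceeded that of all tested genes. The excess was at most 0.54 in 10000 random lists. These add no separate support, since the list had already passed camera, which compares it with other genes, and random genes were drawn independently. The rise did not rest on 1 sporulating library alone. The list's medians over the unsporulated mean were 1.48 and 2.49 in the 2 libraries. The lower one exceeded, though not by much, the median absolute difference of the members between the unsporulated libraries, 1.08. The signed median of unsporulated library 2 minus library 1 was -0.42. A hypothesis is that rhoptry transcripts may accumulate as sporulation starts, which was found and tested on the same data.

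The 2 sporulating libraries differed more from each other than the pairs of the other groups by some measures. Their chi-square per gene was 699, against 212 for unsporulated and 185 for sporulated oocysts. Their median absolute log2 difference was 0.51, against 0.32 and 0.28. By the Pearson correlation of log2 values the unsporulated pair was the least alike, with 0.964 against 0.968 for the sporulating and 0.982 for the sporulated pair. Loss of transcripts by gene length in 1 library was not seen with lengths that include introns. Library 2 minus library 1 had a Spearman correlation with length of 0.0118 across genes (95% bootstrap interval -0.0115 to 0.0352). The unsporulated and sporulated pairs had -0.162 and -0.376. Transcript lengths without introns were not available, so loss by transcript length is not excluded. Different progress along the change seen at 8 h may contribute. Sporulating library 2 minus library 1 had a Spearman correlation of 0.197 (95% bootstrap interval 0.173 to 0.22) with library 1 minus the unsporulated mean. Library 1 enters both with opposite signs, which by itself pulls the correlation below 0. Simulated unchanged groups gave -0.538 (-0.555 to -0.514). Real genes changed at 8 h, which weakens that pull, so the simulated value is no fair reference and only the sign is read here. Different progress toward the sporulated profile stays open: its correlation of 0.0927 (0.0698 to 0.115) lay above 0, but far under the 0.3 set for it as the cause and across the 0.1 set for its exclusion. Separate cats or cultures for the 2 libraries remain open and untested.

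Cytosolic ribosomal protein genes were higher in sporulated than in sporulating oocysts, with median normalized counts of 4300 against 636. Gene length alone does not account for the list's median of 2.51, since 10000 length-matched lists had a median of -0.05 (highest 2.11). The list's percentile of 100 overstates the certainty, because genes were drawn independently while list members vary together (estimated correlation 0.375). The genes are short (median 2780 bases against 5041, with introns), and short genes were higher in sporulated library 2 than in library 1 (correlation with length -0.376). Between the groups, however, the change had a Spearman correlation of 0.0979 with length across genes. Shorter genes in general thus did not rise more. A part played by transcript length, without introns, was not tested. A low starting level alone does not account for the list's median either, since 10000 lists matched on the unsporulated level had a median of 0.27 (highest 1.47). The same limit holds for the list's percentile of 100 there. Scaling moves all genes alike, so it cannot give the 2.34 by which the list's median exceeded that of all tested genes. The excess was at most 1.76 in 10000 random lists, which add no separate support, since the list had already passed camera. A hypothesis is that sporulated oocysts may hold more ribosomal protein mRNA relative to other mRNA than sporulating oocysts, with medians of 2.34 and 2.65 in the 2 sporulated libraries.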
